A study of Rattus norvegicus with 16 samples.

How the data were processed

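RNA from flash-frozen liver of male rats aged 13 weeks was sequenced in 16 libraries, 4 in each of 4 groups. The rats had been sham-operated (SHAM) or adrenalectomized (ADREX, adrenal glands removed) and then spent 4 hours in air or in ozone at 0.8 ppm. Per the labels' protocols, mRNA was selected, libraries were prepared with a Wafergen PrepX kit, and sequencing was done on a NextSeq 500. Per the submitters' processing notes, Partek and DESeq2 were used with the rat genome build rn6. The versions of both, the aligner, the counting method and the annotation are not given in the sources used here.

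The deposited table holds signal values, read counts that the authors had divided by 1 size factor per library, for 22587 gene symbols and 16 libraries. Dividing each column by its step recovered whole reads: 100% of values lay within 0.01 of a whole number, and the largest deviation was 0.000132. Recovered totals ranged from 8372891 to 14096246 reads per library. Levels in RPM are recovered reads scaled to a library total of 1000000 reads, and 3 reads, the upper limit that a count of 0 allows, corresponded to 0.213 to 0.358 RPM. Such limits cover counting error only, because reads without molecular identifiers are not independent molecules. The table gives symbols without positions or identifiers. Of these symbols, 15865 matched a current rat symbol, 1160 matched a synonym only and 5562 matched neither, and 2 symbols that a spreadsheet had turned into dates stood in 4 places. No column was left out, and 2206 genes had 0 reads in all libraries.

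Libraries were grouped by their titles. The labels' treatment field gives ozone for all 8 ADREX libraries, including the 4 whose titles give air, against the titles and the series' description of its design. The labels hold 13 distinct library index numbers, of which 3 were used by 2 libraries each, and give no sequencing batch or date. Replicate numbers differ between all groups, so no pairing of libraries was available.

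Values were transformed as log2(value + 1). Genes with a mean over all libraries of at least 14.7, or 1 count in 1000000 of the median column total, were tested: 12791 genes. The test was limma-trend 3.58.1 in R 4.3.3, two-sided, with a model of 4 group means over the 16 libraries (12 residual and 4.4 prior degrees of freedom), and Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The 5 comparisons were ozone against air in SHAM, ozone against air in ADREX, the difference between those effects, and ADREX against SHAM in air and under ozone. All adjusted p-values for genes and gene lists come from limma unless another tool is named. Errors of log2 changes are standard errors (SE) and errors of group means are standard deviations (SD, n = 4). Normalized counts are the deposited values, and RPM were computed from the recovered reads.

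The tests, the comparisons, most of the alternative settings, 19 pathway lists and 14 cell type lists were chosen before the data were examined. Of 521 list members, 505 were in the table. Lists were tested with limma's camera at a preset correlation of 0.01 and at an estimated correlation, and with fry, each adjusted over the lists of a comparison. Camera needs at least 3 tested members, which left 29 lists. Genes were named by a rule: those that passed the test, whose 4 and 4 libraries did not overlap, with a mean of at least 73.4 (5 counts in 1000000) in the higher group and a symbol that is not a placeholder, up to 10 with the largest rise and 10 with the largest fall. For the difference in ozone effect the condition on overlap does not apply. Members of a list are named where the list is described, and results that concern withheld items were left out. Among the genes tested, 1214 carried placeholder symbols.

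Transcripts of nervous tissue were noticed in the table, and a list of 25 neuron and oligodendrocyte markers was then written. A neural score was computed per library as log2 of their summed RPM plus 1. A gene is said to follow the score when its correlation with it within groups was above 0.7. This held for 1205 genes tested. Genes with 0 reads in 1 library and at least 100 in another of the same group, 41 of those tested, are called all-or-none.

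The alternatives among these were another pseudocount, no filter or a stricter filter on low values, rescaling by TMM or by median of ratios, array quality weights, a robust fit, a fit to the groups of the comparison alone, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, other thresholds, and leaving out each library in turn. Alternatives chosen after the data were seen were the neural score as a covariate, and leaving out the genes that follow it, the 3 libraries richest in neural markers, or the all-or-none genes. On the recovered reads edgeR called 176 genes for ozone in SHAM, 49 for ozone in ADREX, 24 for the difference, 378 for ADREX against SHAM in air and 1585 under ozone. DESeq2 called 540, 570, 248, 835 and 2193 in the same order, beside 202, 16, 14, 451 and 1601 with limma.

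The procedure was tested on simulated data with the mean levels and within-group spread of all 16 libraries. Genes were drawn independently, so its false calls do not cover variation that many genes share, such as that of the neural markers. Of 100 genes changed 2-fold, limma called 37, and of 100 changed 4-fold it called 90, with 7 false calls. It made 0 calls where nothing had been changed, with 4.9% of genes at an unadjusted p under 0.05. On the same simulated changes edgeR called 36 and 90 with 7 false calls, and DESeq2 called 53 and 92 with 25 false calls. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.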

Results

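Liver mRNA was sequenced in 16 libraries, 4 each from sham-operated (SHAM) and adrenalectomized (ADREX) male rats that had breathed air or ozone, an oxidant gas that irritates the airways. The series asks how adrenal stress hormones, which ozone exposure is known to release, regulate liver genes. Recovered reads numbered 9532009, 12548669, 11804832 and 8372891 in SHAM air libraries 1 to 4. They numbered 9742436, 10904748, 14096246 and 10067954 in SHAM ozone libraries 17 to 20. In ADREX air libraries 65 to 68 they numbered 11368856, 12444319, 10089115 and 11985839, and in ADREX ozone libraries 81 to 84 12678751, 11809963, 12740130 and 10575591. Between 15224 and 17439 genes had a read in a library. Spearman's rho across genes was 0.947 to 0.974 between libraries of 1 group and 0.904 to 0.974 between libraries of different groups. Values are normalized read counts, identified by the gene symbols of the deposited table, which gives no positions.

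All libraries held transcripts of neurons and of oligodendrocytes, the cells that make myelin in the brain and spinal cord. Mbp, which encodes a myelin protein, and Snap25, which encodes a synaptic protein, varied widely between libraries. Mbp ranged from 6.29 to 1339 RPM (recovered reads scaled to 1000000 per library) and Snap25 from 0.558 to 206. The summed level of 25 neuron and oligodendrocyte markers was 276 ± 406 RPM in SHAM air, 988 ± 1359 in SHAM ozone, 584 ± 451 in ADREX air and 2178 ± 1922 in ADREX ozone (mean ± SD, n = 4 each). The 3 highest libraries were ADREX ozone 82 at 4934, SHAM ozone 18 at 2996 and ADREX ozone 81 at 2056. The lowest was SHAM air 2 at 45.9. The first principal component, the axis of largest variation over the genes tested, held 48.1% of the variance. Its lowest value was −91.52 in SHAM air 2 and its highest 104.4 in ADREX ozone 82, the libraries with the lowest and highest marker sum. ADREX ozone 81 stood at 67.51 and SHAM ozone 18 at 40.56, and a correlation with the sum was not computed. A difference of the score between the 4 groups was not established (permutation test over 100000 resamples, p = 0.0643). Between pairs of groups, exact permutation tests gave two-sided p = 0.286 for ozone against air in SHAM, 0.0857 for ozone against air in ADREX, 0.143 for ADREX against SHAM in air and 0.2 under ozone. Adjusted over these 4 tests, the values were 0.286, 0.267, 0.267 and 0.267.

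**Figure D1:**
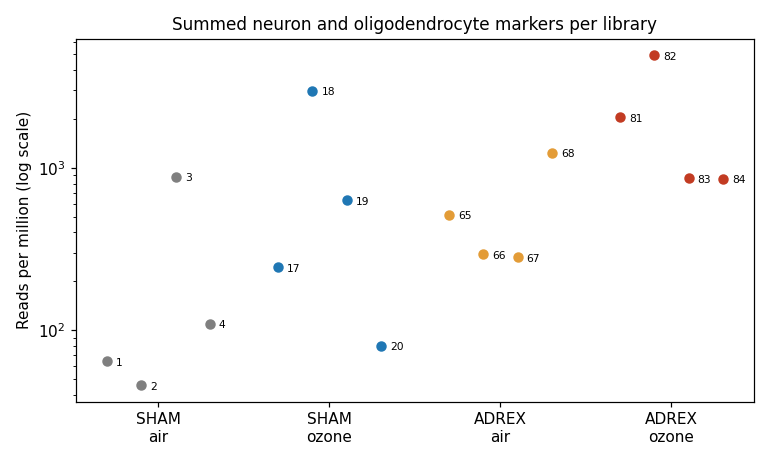
Summed neuron and oligodendrocyte markers in each library, in recovered reads scaled to 1000000 per library (RPM) on a log axis, by group, each point carrying its replicate number. Levels differ within every group, from 45.9 in SHAM air 2 to 4934 in ADREX ozone 82.

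What ozone did to the liver of rats with adrenal glands is shown by SHAM ozone against SHAM air. Slc12a3, a sodium and chloride cotransporter best known from the kidney, rose 28.7-fold, from 8.46 ± 2.50 to 271 ± 72.8 (mean ± SD, n = 4 per group; log2 4.84 ± 0.49, adjusted p = 0.000307). Fkbp5, a chaperone that the glucocorticoid receptor induces, rose from 481 ± 88.8 to 2104 ± 693 (log2 2.08 ± 0.30, adjusted p = 0.00287). Sds, an enzyme that turns serine into pyruvate for glucose synthesis, rose from 338 ± 112 to 3497 ± 927 (adjusted p = 0.00766). Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 320 ± 135 to 2266 ± 1072 (log2 2.78 ± 0.48, adjusted p = 0.00879). Bach2, a transcriptional repressor studied mainly in lymphocytes, rose from 20.1 ± 6.77 to 123 ± 12.3 (log2 2.61 ± 0.30, adjusted p = 0.000486). In each of these 5 genes the 4 ozone libraries were all above the 4 air libraries.

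Further genes that rose were Tpte2 (40.2-fold), Spsb4 (9.96-fold), Car12, a carbonic anhydrase (9.62-fold), Got1, an aspartate aminotransferase (5.70-fold), and Por, the electron donor of the cytochrome P450 enzymes (4.57-fold). Pdzrn3 fell by 1.80 on the log2 scale (adjusted p = 0.00541) and Chka, which encodes choline kinase, fell by 1.75 (adjusted p = 0.00767). All of these genes passed in every alternative setting that tested them, including without any 1 library of the groups compared. Of the 20 genes that the naming rule gave, 10 did so. The others were Fam69c and Spsb1, up, and Akap5, Arhgap6, Osgin1, Lama3, Spon2, Ednra, MGC108823 and Klf12, down. In all, 202 of 12791 genes changed (1.58%), 121 up and 81 down. Of the 202, 1 followed the neural score, and of all genes tested 1205 did. Genes that follow the score have a large spread within groups and are rarely called. Their number among the calls therefore does not measure how far neural RNA shaped the result. With the neural score as a covariate 178 genes were called, and 129 of the 202 stayed called. Without the 3 libraries richest in neural markers 107 were called, and 96 of the 202 stayed called. The share that was up, 59.9%, became 84.2% without SHAM ozone 20. The count depended on single libraries: it was 49 without SHAM air 2, 658 without SHAM air 3, 102 without SHAM air 4, 50 without SHAM ozone 17, 129 without SHAM ozone 18 and 38 without SHAM ozone 20. Another split of these 8 libraries, SHAM air 1, 2 and 4 with SHAM ozone 20 against the rest, gave 563 genes, of which 95.2% correlated with the neural score within groups beyond 0.7 in either direction.

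Among 22 genes of amino acid catabolism and the urea cycle, 1 rose over all genes tested (Sds), and 7 rose when adjusted over the list alone: Sds, Asl, Slc38a4, Tdo2, Tat, Slc7a2 and Arg1. The list's median log2 change was 0.37, above that of other genes (camera adjusted p = 0.00017, but adjusted p = 0.776 with an estimated correlation). Of 25 glucocorticoid receptor targets, Fkbp5 and Agt, the precursor of angiotensin, rose over all genes, and 4 did when adjusted over the list alone, yet the list as a set did not stand out (camera adjusted p = 0.247). Agt rose by 1.25 ± 0.22 on the log2 scale (adjusted p = 0.011), which became 0.0516 without SHAM air 2 and 0.0597 without SHAM ozone 20. Genes of the interferon response had a median of −0.59 (camera adjusted p = 0.00017). With an estimated correlation the adjusted p was 0.776, and with the neural score as a covariate the median was −0.246 and the adjusted p 0.0574. Of its 19 members limma called 0 over all genes tested, with 9 at an unadjusted p under 0.05, edgeR called 0 and DESeq2 called 1. Adjusted over the list alone 5 fell, among them Ifit3, Mx1, Ifi44 and Gbp2. Sinusoidal endothelial markers, of the cells that line the liver's capillaries, had a median of −0.35 over 9 members (camera adjusted p = 0.0219, and adjusted p = 0.776 with an estimated correlation), a call that was lost without SHAM ozone 18 (0.222) and with the neural score as a covariate (0.25). Of these members limma, edgeR and DESeq2 called 0, with 3 at an unadjusted p under 0.05.

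**Figure D2:**
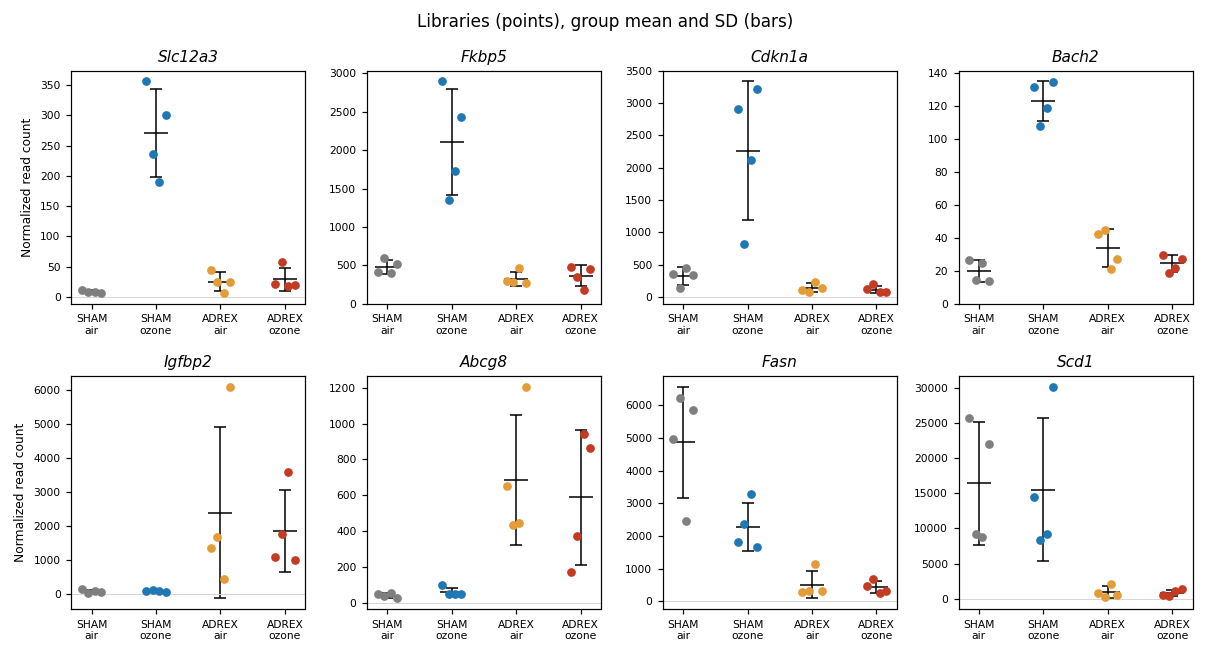
Normalized read counts of 8 genes in each of the 16 libraries (points), with the mean and SD of each group of 4, for SHAM and ADREX in air and ozone. Slc12a3, Fkbp5, Cdkn1a and Bach2 are higher in SHAM ozone than in the other groups, Igfbp2 and Abcg8 are higher in both ADREX groups, and Fasn and Scd1 are lower in both ADREX groups.

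In adrenalectomized rats limma called 16 genes changed with ozone. Scrn1, which encodes secernin, rose from 78.8 ± 25.3 to 362 ± 115 (n = 4 per group, log2 2.19 ± 0.35, adjusted p = 0.0352). Prox1, a transcription factor of hepatocytes and lymphatic vessels, fell from 3244 ± 419 to 1558 ± 325 (log2 −1.07 ± 0.18, adjusted p = 0.0352), and Tmem2, a cell surface hyaluronidase, fell from 1814 ± 457 to 768 ± 245 (log2 −1.26 ± 0.22, adjusted p = 0.0352). Of 12791 genes these 16 were 5 up and 11 down, and 2282 had an unadjusted p under 0.05, against 2358 for ozone in SHAM. The other genes named by the rule were Morn4, Baiap3, Tubb2a and Ciapin1, up, and Atmin, Zbtb20, Acvr1c, Bdp1, Rc3h1, N4bp2, Kdm7a and Ash1l, down. Morn4 and Baiap3, which are active in neurons, followed the neural score (r = 0.76 each), and the marker sum averaged 2178 RPM in ADREX ozone and 584 in ADREX air. Atmin had 618 ± 49.6 in ADREX air and 0 reads in all 4 ADREX ozone libraries. It also had 0 reads in all 4 SHAM ozone libraries, and 284 ± 328 in SHAM air. Such all-or-none values also occurred between libraries of 1 group, so its fold change is not given.

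None of these 15 genes passed the test in every alternative setting. With the neural score as a covariate 11 of the 16 calls stayed, and without the 3 libraries richest in neural markers 1 stayed. With limma the count was 0 without ADREX air 65 or 66 or without ADREX ozone 82 or 84 (1718, 1503, 1568 and 2242 genes at an unadjusted p under 0.05), 3 without ADREX ozone 83, 50 without ADREX air 67 and 27 without ADREX air 68. Because the fit shares its estimate of spread, SHAM libraries mattered too. The count was 0 without SHAM ozone 17, 19 or 20 (2114, 2170 and 2258 at an unadjusted p under 0.05), 4 without SHAM air 1 and 7 without SHAM ozone 18. For Scrn1 the adjusted p was 0.156 without ADREX air 65, 0.142 without ADREX air 66, 0.138 without ADREX ozone 82 and 0.0862 without ADREX ozone 84, and Prox1 had the same values. For Tmem2 it was 0.156, 0.151, 0.109 and 0.0862 without these libraries and 0.11 without ADREX ozone 83. In this comparison edgeR called 49 genes and DESeq2 570, against 176 and 540 for ozone in SHAM, and rescaling by TMM gave 4 up and 15 down and by median of ratios 4 up and 16 down. The share that was up, 31.2%, became 63.9% of 36 genes with no filter on low values and 50% of 26 with a pseudocount of 10.

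Genes of insulin, insulin-like growth factor and growth hormone signalling had a median log2 change of −0.33 with ozone in ADREX (19 members, camera adjusted p = 0.000495, adjusted p = 0.634 with an estimated correlation and 0.0733 with the neural score as a covariate). Insr, the insulin receptor, and Irs1, its docking protein, fell when adjusted over the list alone. Over all genes limma called 0 members, with 6 at an unadjusted p under 0.05, edgeR called 0 and DESeq2 called 2. Genes of the cAMP and immediate early response, such as Egr1 and Junb, had a median of −0.45 over 16 members (camera adjusted p = 0.00334, and adjusted p = 0.634 with an estimated correlation). Limma and edgeR called 0 of them, with 5 at an unadjusted p under 0.05, and DESeq2 called 2. Cholesterol synthesis genes had a median of −0.36 over 23 members (camera adjusted p = 0.00334, and 0.707 with an estimated correlation). That result rested on ADREX air 67, without which the median was 0.02 and the adjusted p 0.513. The adjusted p was 0.466 with array quality weights, 0.242 with the neural score as a covariate and 0.0841 without the 3 libraries richest in neural markers. The 3 tools called 0 of these members, with 1 at an unadjusted p under 0.05. Sinusoidal endothelial markers had a median of −0.42 (camera adjusted p = 0.0122, 0.707 with an estimated correlation, 0.256 with the neural score as a covariate and 0.153 without ADREX air 65). Without ADREX air 65 the median was −0.2. Of 9 members edgeR and DESeq2 called 0, with 2 at an unadjusted limma p under 0.05.

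Whether the ozone effect depended on the adrenal glands was tested as a difference between the effects. Bach2, Spsb4 and Epb4.1 rose with ozone in SHAM by 2.61, 3.32 and 1.57 on the log2 scale, against changes of −0.40, −0.69 and −0.80 in ADREX. Their differences were −3.01 ± 0.42 (adjusted p = 0.00871), −4.00 ± 0.53 (adjusted p = 0.00707) and −2.37 ± 0.32 (adjusted p = 0.00707), and they passed in every alternative setting. Of the 13 genes that the naming rule gave for the difference, only these 3 did so. Epb4.1 encodes a protein of the membrane skeleton, and Spsb4 a component of ubiquitin ligases. In air Bach2, Spsb4 and Epb4.1 averaged 20.1, 37.5 and 656 in SHAM and 33.7, 210 and 1168 in ADREX. Under ozone they averaged 123, 433 and 1955 in SHAM and 24.5, 141 and 648 in ADREX. Their differences thus draw on a higher mean in ADREX air as well, and selection by the difference favours such genes. The cotransporter gene Slc12a3 rose by 4.84 in SHAM and changed by 0.33 in ADREX, where its means were 24.9 ± 15.8 in air and 29.2 ± 19.01 with ozone. Its difference of −4.51 ± 0.69 had an adjusted p of 0.0193, which became 0.0704 without SHAM ozone 17, 0.0759 without SHAM ozone 20, 0.0573 without ADREX air 66, 0.0551 without ADREX ozone 83 and 0.0662 without ADREX ozone 84.

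The difference passed for 14 genes, 11 with a negative value and 3 with a positive value (Tmem159, Mettl6 and Ift20). The remaining genes were Slc16a10, Por, Dcaf13, Prox1, Cdk19, Lats1 and Dag1. The count was 33 without SHAM air 3, 29 without ADREX ozone 81, 8 without SHAM air 4, 6 without SHAM ozone 19 or ADREX ozone 82, 5 without SHAM air 2 and 4 without ADREX air 65. It was 3 without SHAM ozone 17 or 20, ADREX air 66, or ADREX ozone 83 or 84. Of the 202 genes that ozone changed in SHAM, 129 (63.9%) moved the same way in ADREX and 73 the opposite way. The difference passed for 148 of them when adjusted over those genes alone, all with a smaller or reversed response in ADREX, but a selection by the SHAM effect favours such differences. Only 1 gene was called in both ozone comparisons, against 0.25 for independent calls (Fisher's exact test, p = 0.225), and it rose in both, against 0.05 for independent rises (p = 0.0464). The test takes genes as independent, which they are not. Glucocorticoid receptor targets had a median difference of −0.47 (camera adjusted p = 0.00571, 0.653 with an estimated correlation, 0.073 without SHAM air 3 and 0.0527 with the stricter filter), and Fkbp5 and Agt differed when adjusted over the list alone. Over all genes limma and edgeR called 0 of them, with 5 at an unadjusted p under 0.05, and DESeq2 called 2. Amino acid catabolism genes had a median difference of −0.44 (camera adjusted p = 0.00571, 0.653 with an estimated correlation, 0.0754 without SHAM air 3 and 0.0527 with the stricter filter). Limma called 0 of them over all genes and over the list alone, with 6 at an unadjusted p under 0.05, edgeR called 0 and DESeq2 called 2.

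**Figure D3:**
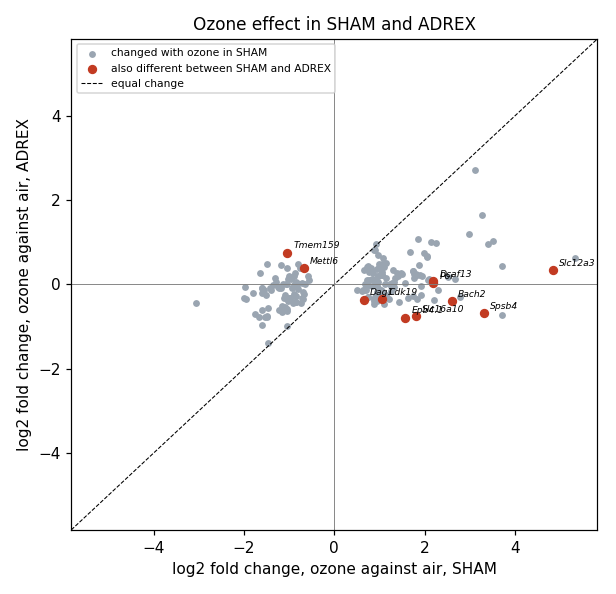
Log2 change with ozone in SHAM (horizontal) and in ADREX (vertical) of the 202 genes that ozone changed in SHAM, with a dashed line where both changes are equal. Genes whose difference passed over all genes are red, and 129 of the 202 have the same sign in both.

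In air some of the genes that make fat from glucose were lower in ADREX than in SHAM. Fasn, fatty acid synthase, fell from 4877 ± 1702 in SHAM air to 507 ± 424 in ADREX air (n = 4 per group, log2 −3.47 ± 0.43, adjusted p = 0.000558). Scd1, a fatty acid desaturase, fell from 16414 ± 8715 to 897 ± 867 (log2 −4.57 ± 0.64, adjusted p = 0.00104). Igfbp2, a carrier of insulin-like growth factors, rose from 75.7 ± 50.1 to 2394 ± 2526 (24.3-fold, adjusted p = 0.000906). Abcg8 and Abcg5, which together export sterols into bile, rose 15.7-fold and 9.15-fold. Cyp4a8, a cytochrome P450 of fatty acid hydroxylation, fell 13.5-fold (adjusted p = 5.21e-05).

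Of 18 lipogenesis genes 9 fell over all genes tested and 14 when adjusted over the list alone, with a median of −1.25 (camera adjusted p = 2.01e-14, and adjusted p = 0.0774 with an estimated correlation). They included Acaca, Acly, Thrsp and Pklr. Of 11 glycogen metabolism genes 2 rose and 5 fell over all genes, and 2 rose and 6 fell when adjusted over the list alone (median −0.49, camera adjusted p = 0.00163, and adjusted p = 0.0774 with an estimated correlation). Gbe1, the glycogen branching enzyme, and the phosphatase subunits Ppp1r3b and Ppp1r3c fell, while Gys2, the liver's glycogen synthase, rose by 1.73. Cholesterol synthesis genes had a median of −1.01 over 23 members (camera adjusted p = 8.45e-09, and adjusted p = 0.391 with an estimated correlation). Hmgcs1 fell over all genes tested (adjusted p = 0.0467), and 11 fell when adjusted over the list alone. The call of Hmgcs1 was lost without SHAM air 1 (0.0764), 2 (0.122) or 4 (0.11) and without ADREX air 65 (0.135), 66 (0.145) or 68 (0.142). Of 17 genes of bile acid synthesis and transport 2 rose, Abcg5 and Abcg8, and 3 fell, and 2 rose and 6 fell when adjusted over the list alone. Their median was −0.35 and their mean 0.08, and camera made no call (adjusted p = 0.213).

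Genes of fatty acid oxidation, ketogenesis and PPAR alpha were called higher in ADREX air by camera at its preset correlation only. Of 24, 4 rose over all genes (among them Vnn1, Cyp4a1 and Ehhadh), and 14 rose and 1, Plin2, fell when adjusted over the list alone (median 0.52, camera adjusted p = 0.00163, and adjusted p = 0.391 with an estimated correlation). The 4 became 2 without SHAM air 2, ADREX air 65 or ADREX air 66, 11 without SHAM air 3 and 10 without ADREX air 67. Of 16 genes of the cAMP and immediate early response 4 rose over all genes (Btg2, Junb, Klf4 and Sik1), and 10 rose and 1 fell when adjusted over the list alone (median 1.08, camera adjusted p = 0.000564, and adjusted p = 0.243 with an estimated correlation). The 4 became 2 without SHAM air 1 or ADREX air 66, and 1 without SHAM air 4 or ADREX air 65. Of 25 glucocorticoid receptor targets 2 rose and 1 fell over all genes, and 3 rose and 4 fell when adjusted over the list alone, with no call by camera (adjusted p = 0.575). Igfbp1 rose by 2.16, and Sgk1, a kinase that glucocorticoids induce, rose by 2.59 rather than falling (adjusted p = 0.0284). For Sgk1 the adjusted p was 0.0984 without SHAM air 2, 0.105 without SHAM air 4, 0.0649 without ADREX air 66 and 0.0559 without ADREX air 68. The 3 became 1 without SHAM air 2, SHAM air 4, ADREX air 66 or ADREX air 68, and 5 without SHAM air 3.

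Camera also called lists of cell type markers in ADREX air. Markers of Kupffer cells, the liver's macrophages, had a median of 0.44 (camera adjusted p = 0.0188, 0.519 with an estimated correlation, 0.0903 without SHAM air 3 and 0.087 without ADREX air 65). Of these 11 markers limma, edgeR and DESeq2 called 0, with 4 at an unadjusted p under 0.05. Camera called 4 more lists, gluconeogenesis, NF-kB signalling, cholangiocytes and B cells, at adjusted p of 0.0441, 0.0428, 0.0428 and 0.0473, and with an estimated correlation these were 0.391, 0.243, 0.238 and 0.374. Gluconeogenesis lost its call without SHAM air 1 (0.116), SHAM air 3 (0.0903), ADREX air 66 (0.0888) or ADREX air 67 (0.164), with the stricter filter (0.0932), array quality weights (0.0937) or the neural score as a covariate (0.0818), and without the genes that follow the score (0.0799). NF-kB signalling lost it without SHAM air 1 (0.0517), SHAM air 3 (0.207), ADREX air 65 (0.0528) or ADREX air 67 (0.143), and with no filter (0.137) or array quality weights (0.112). Cholangiocyte markers lost it without SHAM air 1 (0.0517), SHAM air 3 (0.0903), ADREX air 65 (0.055) or ADREX air 67 (0.119), with array quality weights (0.11), and without the genes that follow the score (0.0771). B cell markers lost it without SHAM air 1 (0.116), SHAM air 3 (0.0903), ADREX air 65 (0.087) or ADREX air 68 (0.065), and with a pseudocount of 0.1 (0.0502), no filter (0.133), array quality weights (0.0549), the 2 groups fitted alone (0.0571), the neural score as a covariate (0.0722) or the 3 richest libraries left out (0.0518).

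In all, 451 genes differed between ADREX and SHAM in air (3.53%), 191 up and 260 down. The share that was up, 42.4%, became 61.7% without SHAM air 3 and 53.4% with array quality weights. Of the 451, 5 followed the neural score, a count with the same limit as for ozone in SHAM. The marker sum averaged 584 RPM in ADREX air and 276 in SHAM air. With the neural score as a covariate 194 genes were called, and 187 of the 451 stayed called. The count was 228 without SHAM air 2, 1004 without SHAM air 3, 206 without SHAM air 4, 255 without ADREX air 65, 194 without ADREX air 66, 824 without ADREX air 67 and 246 without ADREX air 68. Another split of these 8 libraries, SHAM air 1, 2 and 4 with ADREX air 67 against the rest, gave 1422 genes. Fasn, Scd1, Igfbp2, Abcg8, Abcg5 and Cyp4a8 passed in every alternative setting, and 17 of the 20 genes that the naming rule gave did so.

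**Figure D4:**
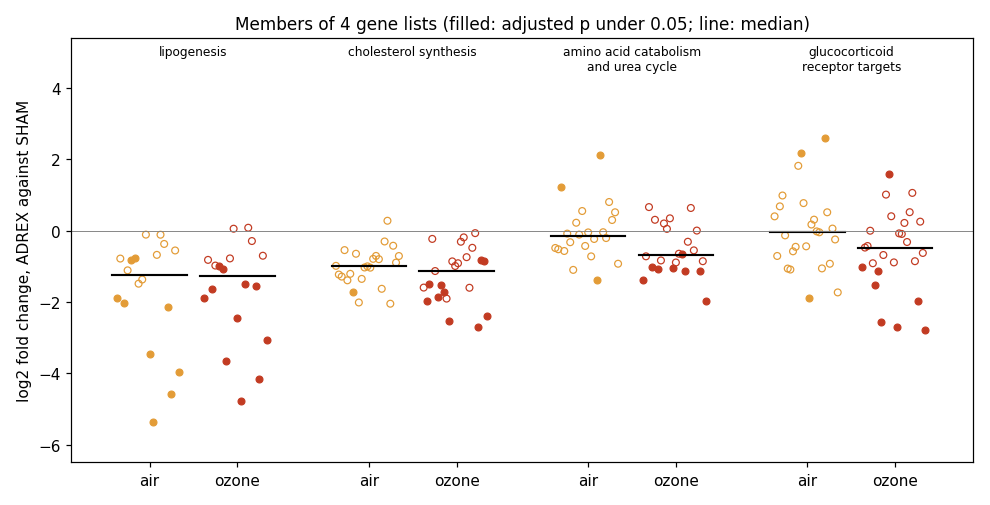
Log2 change of each member of 4 gene lists between ADREX and SHAM, in air and under ozone, with filled points for members that passed over all genes and a line at the list's median. Lipogenesis has medians of −1.25 in air and −1.28 under ozone, and cholesterol synthesis −1.01 and −1.14.

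Under ozone more genes separated adrenalectomized from sham-operated rats. Fkbp5 was lower in ADREX ozone (365 ± 137) than in SHAM ozone (2104 ± 693; n = 4 per group, log2 −2.56 ± 0.30, adjusted p = 0.000211). Cdkn1a averaged 2266 ± 1072 in SHAM ozone and 113 ± 56.8 in ADREX ozone (log2 −4.26 ± 0.48, adjusted p = 0.000139), and Car12 averaged 854 ± 328 in SHAM ozone and 20.7 ± 14.97 in ADREX ozone (log2 −5.48 ± 0.54, adjusted p = 4.96e-05). Tdo2, which breaks down tryptophan, and Zbtb16, a transcription factor induced by glucocorticoids, had log2 changes of −1.99 ± 0.30 and −2.79 ± 0.61 (adjusted p = 0.000846 and 0.00793). Igfbp2, Serpina7, Abcg5 and Abcg8 rose 19.4-fold, 17.7-fold, 11.1-fold and 7.97-fold, and Cyp4a8 fell 23.7-fold (adjusted p = 2.84e-06). Edem1, of the degradation of misfolded proteins, fell 14.4-fold and Etnppl, of phospholipid breakdown, 16.3-fold. These genes passed in every alternative setting, and 16 of the 20 genes that the naming rule gave did so.

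Of 25 glucocorticoid receptor targets 1 rose and 7 fell over all genes, and 1 rose and 9 fell when adjusted over the list alone (median −0.48, camera adjusted p = 0.00261, and adjusted p = 0.338 with an estimated correlation). The 8 became 5 without SHAM ozone 20. Of 22 genes of amino acid catabolism and the urea cycle 8 fell over all genes, and 1 rose and 11 fell when adjusted over the list alone (median −0.69, camera adjusted p = 0.000384, and adjusted p = 0.352 with an estimated correlation). The 8 became 3 without SHAM ozone 17 or ADREX ozone 82, 2 without SHAM ozone 20, and 5 without SHAM ozone 19, ADREX ozone 81 or ADREX ozone 83. Of 15 gluconeogenesis genes 4 fell over all genes and 5 when adjusted over the list alone, among them Foxo1 and Mdh1 (median −0.69, camera adjusted p = 0.000244, and adjusted p = 0.212 with an estimated correlation). Of 19 insulin and growth factor signalling genes 2 rose and 6 fell over all genes and over the list alone, among them Igfbp2, up, and Insr, Pik3r1 and Igfbp3, down (median −0.26, camera adjusted p = 0.0159, 0.352 with an estimated correlation, 0.105 with the neural score as a covariate, 0.0787 with the stricter filter and 0.0647 without ADREX ozone 82). The 8 became 5 without SHAM ozone 20.

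Some lipogenesis and cholesterol synthesis genes were also lower in ADREX under ozone. Of 18 lipogenesis genes 11 fell over all genes and 12 when adjusted over the list alone, Fasn by −2.45 on the log2 scale (median −1.28, camera adjusted p = 4.31e-11, and adjusted p = 0.212 with an estimated correlation). Of 23 cholesterol synthesis genes 10 fell over all genes and 17 when adjusted over the list alone (median −1.14, camera adjusted p = 6.48e-10, and adjusted p = 0.352 with an estimated correlation). The 10 became 4 without SHAM ozone 17 or 19, 5 without SHAM ozone 20 or ADREX ozone 82, and 6 without ADREX ozone 83. Of 11 glycogen metabolism genes 2 rose and 4 fell, and 3 rose and 5 fell when adjusted over the list alone (median −0.38, camera adjusted p = 0.0164, 0.217 with an estimated correlation and 0.0597 without the 3 libraries richest in neural markers). Of 5 T and NK cell markers 3 rose over all genes (Cd8a, Nkg7 and Prf1) and 4 when adjusted over the list alone (median 1.001, camera adjusted p = 0.0159, 0.279 with an estimated correlation and 0.106 without those 3 libraries). The 3 became 1 without SHAM ozone 17, 18 or 20, or without ADREX ozone 81, 82 or 83. Of 11 Kupffer cell markers 3 rose over all genes (C1qa, Clec4f and C1qb), of which C1qa passed in every alternative setting, and of 3 B cell markers 2 rose (Jchain and Cd74), neither in every setting. Camera called neither list (adjusted p = 0.0713 and 0.0513). Periportal hepatocyte markers had a median of −0.32 (camera adjusted p = 0.026, 0.419 with an estimated correlation, 0.195 without the 3 libraries richest in neural markers, 0.0794 with the neural score as a covariate, 0.0892 with the stricter filter, 0.0619 without SHAM ozone 20, 0.108 without ADREX ozone 81 and 0.064 without ADREX ozone 82), and 2 of 11 fell over all genes, among them Cps1, the first enzyme of the urea cycle, and 3 when adjusted over the list alone. Sds, which ozone had raised in SHAM, did not pass (adjusted p = 0.739).

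In all, 1601 genes differed between ADREX and SHAM under ozone (12.52%), 772 up and 829 down. Rescaling moved that split, to 559 up and 1131 down with TMM and to 579 up and 1058 down with median of ratios. The share that was up, 48.2%, became 58.8% with array quality weights and 54.7% without SHAM ozone 18. Of the 1601, 85 that rose and 5 that fell followed the neural score, counts with the same limit as for ozone in SHAM. In either direction 6.7% of the 1601 correlated with the score beyond 0.7, against 10.4% of all genes tested. The marker sum averaged 2178 RPM in ADREX ozone and 988 in SHAM ozone. With the neural score as a covariate 1095 genes were called, and 951 of the 1601 stayed called. Without the 3 libraries richest in neural markers 479 were called, and 449 of the 1601 stayed called. The count was 850 without SHAM ozone 17, 787 without SHAM ozone 20 and 993 without ADREX ozone 82.

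The effects of adrenalectomy in air and under ozone, which share no library, overlapped. Igfbp2, Abcg8, Abcg5 and Serpina7 rose in both, and Fasn, Scd1, Stac3, Car12 and Cyp4a8 fell in both. In all 91 genes rose in both, against 11.53 for independent calls (Fisher's exact test, p = 3.76e-60), and 146 fell in both, against 16.85 (p = 2.12e-106). This test takes genes as independent, and the shared estimate of spread favours calls of the same genes in both comparisons, so its p-values overstate the overlap. Of the 451 genes called in air 92.9% had the same sign under ozone. Across all genes tested, which are not independent replicates, the effects had a Pearson correlation of 0.578.

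With an estimated correlation, camera called 0 of 29 lists in every comparison, and 0, 1, 0, 5 and 4 lists had an unadjusted p under 0.05, in the order ozone in SHAM, ozone in ADREX, their difference, ADREX against SHAM in air and under ozone. The fry test, which asks whether a list's genes move one way on balance, called 7 lists in air and 8 under ozone between ADREX and SHAM. For ozone in SHAM, ozone in ADREX and their difference fry called 0, with 5, 3 and 2 lists at an unadjusted p under 0.05. For changes in either direction fry called 12 lists for ozone in SHAM, 18 for ADREX against SHAM in air and 23 under ozone. It called 0 for ozone in ADREX and for the difference, with 2 and 4 lists at an unadjusted p under 0.05.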

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

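The tests chosen after the results were seen are the count of markers higher in the richest library, the Schwann cell share in the other 13 libraries, the comparison of Pmch with Snap25, the count under TMM, the fits with the neural score as a covariate, and the use of the ADREX count split and of the correlation without the covariate in weighing the treatment field.

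Neuron and oligodendrocyte markers, which no comparison of the study concerns, reached 4934 RPM in ADREX ozone 82, and SHAM air 3 had 884 RPM against 45.9 to 110 in the other SHAM air libraries. Of 25 markers 23 were at least 10-fold higher in the richest than in the poorest library. The libraries had been ranked by these same markers, so the count does not test the source. Hypothalamus markers summed to 145.1 RPM in ADREX ozone 82, 86.21 in ADREX ozone 81 and 1.195 in SHAM air 2. They reached 28.52 in SHAM ozone 18, below 49.06 in ADREX ozone 83. Cortex and hippocampus markers did not rise alike, with 215.1 in ADREX ozone 82 and 194.2 in SHAM air 2. The hypothalamus sums go with brain RNA in ADREX ozone 81 and 82. They were not tested, and RNA from brain tissue stays open. For the 3 richest libraries nerve within the liver was argued against. Schwann cell markers, of the cells that make myelin in peripheral nerves, reached at most 2.73% of the central oligodendrocyte markers there. In the other 13 they reached 3.74% to 84.1%. The Schwann cell sum was much the same in both sets, 2.05 to 4.59 RPM in the 3 and 2.03 to 4.31 in the 13. The highest share was in SHAM ozone 20, with a central sum of 4.37 RPM, and the lowest of the 13 in ADREX air 68, with 71.4. The high shares thus came from low central sums, and nerve stays open for such libraries. A single neural RNA shared by all libraries was argued against as well: SHAM ozone 18 had 0 Pmch and 1156 Snap25 reads, and the other SHAM ozone libraries together had 61 and 394 (Fisher's exact test, p = 1.5e-35, which takes reads as independent molecules, and p = 0.00037 on counts divided by 10). How such RNA could have entered, at dissection or in the laboratory, stays open, and a biological source that differs between the groups was tested only by the permutation tests of the score (p = 0.0643 over the 4 groups).

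More genes separated ADREX from SHAM under ozone (1601) than in air (451), and the difference between these counts itself was not tested. Gene by gene, the test of the difference in ozone effect also asks whether the adrenalectomy effect differed between ozone and air. It passed for 14 genes (0.11% of those tested), and 92.9% of the genes called in air had the same sign under ozone. A different effect of adrenalectomy under ozone was thus called for these 14 genes only. Neural RNA as far as the score captures it was not the whole of the excess under ozone. With the neural score as a covariate 1095 genes separated ADREX from SHAM under ozone and 194 in air. Without any 1 library the former count stayed at least 2.52 times the latter. A single score cannot remove neural RNA of several mixtures, so what it misses is not excluded. The libraries richest in neural markers did not set the count more than others: leaving those 3 out gave 479 genes, near the 413 in air, but that ranked 8 among the 24 ways of leaving out 1 SHAM ozone and 2 ADREX ozone libraries (121 to 1333, median 362.5). The authors' scaling is argued against too, since TMM rescaling gave 1690 genes. What stays open is a biological difference, such as adrenal hormones released under ozone, which may separate the groups more. Neural RNA that the score misses and a difference in spread between the air and ozone libraries stay open too.

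Limma called fewer genes for ozone in ADREX (16) than in SHAM (202), but DESeq2 gave 570 and 540, the opposite order, and the difference between the counts was not tested. The neural score did not account for the order with limma: with it as a covariate the counts were 20 in ADREX and 178 in SHAM. A single score cannot remove neural RNA of several mixtures, so spread from such RNA is not excluded. The treatment field of the labels would fit ADREX air libraries that had in fact been exposed to ozone. As predicted for that case, the ADREX change correlated with the SHAM change no more than in other splits of the 8 ADREX libraries (with the neural score as a covariate r = 0.123, highest other 0.297, and 16 of 35 splits as far from 0; without it r = 0.461, highest other 0.624, and 7 of 35). Equal exposure would, however, place the titled split highest in only 1 of 35 cases by chance. Its count was 16 genes, against 1 in the highest other split. That count was brought into the verdict after the correlation was seen, handling that differed between the titled groups would separate them too, and with the covariate another split gave 24 genes against 20, so a wrong title and a loss of the response without adrenal glands cannot be told apart here.

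Other splits of the same libraries were fitted for each comparison. Chance could not be excluded for ozone in SHAM, where 2 of 35 splits gave as many genes: the real one gave 202, and a split of SHAM air 1, 2 and 4 with SHAM ozone 20 against the rest gave 563. That split follows a structure of the samples, since 95.2% of its calls correlated with the neural score within groups beyond 0.7 in either direction and its first side holds the 4 libraries lowest in neural markers. Chance could not be excluded for ADREX against SHAM in air either, where 2 of 35 splits gave as many: the real one gave 451, and a split of SHAM air 1, 2 and 4 with ADREX air 67 gave 1422, with 28.5% of its calls beyond 0.7 in either direction. These are again the 4 libraries lowest in neural markers, and with the neural score as a covariate 1 of 35 splits, the real one, gave as many for each of these comparisons. For ozone in ADREX without the covariate only the real split gave as many as its 16 genes (1 of 35, highest other 1). With the neural score as a covariate 2 of 35 gave as many as the real 20. For ADREX against SHAM under ozone only the real split gave as many (1 of 35, 1601, highest other 2), which argues against chance. A share of 1 in 35 is the smallest that these splits can give, and it was not adjusted over the comparisons. Such a share cannot exclude chance. For the difference in ozone effect 2 of 100 splits gave as many genes as the real 14. These splits shuffled all 16 libraries over the 4 groups, which also breaks up the effects of ozone and of adrenalectomy. They therefore cannot exclude chance for the difference alone. A split with SHAM air 1, 2 and 4 and ADREX ozone 84 as 1 group gave 399, with 0.8% of its calls beyond 0.7 in either direction. That share does not settle whether it follows the neural score, because no split of the difference was fitted with the covariate. With the neural score as a covariate the real splits gave 178, 20, 194 and 1095 genes for ozone in SHAM, ozone in ADREX, and ADREX against SHAM in air and under ozone, and the highest others 3, 24, 5 and 1.

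With libraries grouped by title, the effect of ozone differed between ADREX and SHAM, by the test of the difference itself, for 14 genes. This result carries the doubt about the titles of the ADREX air libraries. The log2 differences were −3.01 for Bach2, −1.41 for Cdk19, −1.02 for Dag1, −2.12 for Dcaf13, −2.37 for Epb4.1, −1.11 for Lats1, −2.17 for Por, −1.42 for Prox1, −4.51 for Slc12a3, −2.57 for Slc16a10 and −4.00 for Spsb4. They were 1.05 for Ift20, 1.06 for Mettl6 and 1.78 for Tmem159. In SHAM Slc12a3, Spsb4, Bach2, Por, Dcaf13, Slc16a10, Epb4.1, Cdk19 and Dag1 rose with ozone, and none of these 9 passed the limma test in ADREX.

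In 18 of 206 groups of 4 values, against 10.3 that chance would give at about 1 in 20 groups, 1 library lay far from the other 3. Besides the neural markers of SHAM air 3 these were 17 values of 16 genes (Car12 in 2 groups), in normalized counts with the range of the other 3 in brackets. In SHAM air, Cdk19 was 270.8 in library 1 (385.6 to 412.5), Serpina7 148.8 in library 1 (337.5 to 358.8), Ppp1r3g 8.408 in library 2 (5.953 to 6.25) and Per3 18.06 in library 4 (52.09 to 63.66). In SHAM ozone, Abcg8 was 96.63 in library 17 (47.88 to 51.62), Klf12 426.6 in library 19 (148 to 166.4), and in library 18 Car12 was 374.3 (946.7 to 1118), Dbp 398.8 (87.06 to 108.7) and Spsb1 35.48 (146.5 to 174.1). In ADREX air, Car12 was 1.059 in library 66 (6.115 to 7.446), Fasn 1142 in library 67 (275.4 to 314.3) and Lats1 546.6 in library 68 (630.8 to 649.3). In ADREX ozone, Slc12a3 was 57.61 in library 82 (18.65 to 21.73), Stac3 0 in library 83 (25.16 to 48.93), Trim36 13.16 in library 83 (36.66 to 44.6), Mettl6 331.0 in library 84 (266.6 to 268.8) and N4bp2 374.2 in library 84 (576.1 to 626.7).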

How the results depend on the processing

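The fits with the neural score, without the genes that follow it, without the 3 richest libraries and without all-or-none genes were chosen after the data were seen. No paired analysis was possible because the replicate numbers of the groups do not correspond. No named gene that had passed reversed its direction under any alternative, and of 231 such results 74 lost their call with the neural score as a covariate, 97 without the 3 richest libraries, 24 with edgeR and, of 229, 0 with DESeq2. Of 30 camera calls 30 were lost with an estimated correlation and 9 with the covariate. The median of cholesterol synthesis genes for ozone in ADREX ranged from −0.567 without ADREX air 68 to 0.021 without ADREX air 67. Counts of changed genes follow in the order ozone in SHAM, ozone in ADREX, their difference, ADREX against SHAM in air and under ozone, where they moved by more than 1.5 times. Array quality weights gave 1133, 330, 182, 1456 and 3414 genes and 35 shared by the ozone comparisons in place of 1. DESeq2 gave 540, 570, 248 and 835, with 27 shared, and in the test on simulated data it made more false calls (25) than limma (7). With edgeR ozone in ADREX gave 49 and the difference 24. An adjusted p under 0.1 gave 504, 149, 46, 848 and 2718, and a minimum change of 2-fold left 125 for ozone in SHAM and 742 for ADREX against SHAM under ozone. For ozone in ADREX a pseudocount of 10 gave 26 and no filter gave 36. Fitting the groups of a comparison alone gave 2 for ozone in ADREX and 212 in air, with 0 shared. The neural score as a covariate gave 22 for the difference and 194 in air, with 3 shared. Without the 3 richest libraries, which leaves 2 in ADREX ozone, ozone in SHAM gave 107, ozone in ADREX 1 and ADREX against SHAM under ozone 479, with 0 shared. The shared gene was also lost (0) with a pseudocount of 0.1, TMM, median of ratios, and without all-or-none genes. For these moves the cause was not tested, except that fewer libraries lower the power. Leaving out 1 library of the groups compared gave 38 to 658, 0 to 50, 3 to 33, 194 to 1004 and 787 to 1692 genes, and 0 to 3 shared. Leaving out other libraries gave up to 1848 under ozone (without SHAM air 3). Depth limits low levels: 0 reads allow up to 0.213 to 0.358 RPM.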

Other observations

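Haemoglobin transcripts varied widely within groups. Hbb averaged 1246 ± 626 normalized counts in SHAM air, 2427 ± 2511 in SHAM ozone, 1280 ± 725 in ADREX air and 1250 ± 1315 in ADREX ozone (mean ± SD, n = 4), and Hba-a2 437 ± 231, 1262 ± 1570, 416 ± 308 and 297 ± 357. The 5 erythroid markers tested had a median of −1.94 between ADREX and SHAM under ozone (camera adjusted p = 0.014, 0.352 with an estimated correlation and 0.151 with the stricter filter) and of −1.996 for the difference in ozone effect (camera adjusted p = 0.0326, and 0.653 with an estimated correlation). The latter call was lost without SHAM air 3 (0.0754), SHAM air 4 (0.0665), SHAM ozone 17 (0.126), ADREX air 67 (0.0633), ADREX ozone 83 (0.0778) or ADREX ozone 84 (0.0721), and with the stricter filter (0.202), TMM (0.0604) or median of ratios (0.0644). Its median was −1.267 without SHAM ozone 17 and −1.28 without ADREX ozone 84. For the difference edgeR and DESeq2 called 0 of the 5 markers, with 1 at an unadjusted limma p under 0.05.

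Cyp17a1, an enzyme of steroid synthesis, averaged 54.5 ± 17.1 normalized counts in SHAM air and 406 ± 364 in ADREX air (log2 2.42 ± 0.59, limma adjusted p = 0.0321). That adjusted p was 0.0628 without SHAM air 1, 0.0573 without SHAM air 2, 0.0777 without SHAM air 4, 0.101 without ADREX air 65 and 0.1 without ADREX air 68. Of the neutrophil markers S100a9 and Csf3r had log2 changes of 1.56 and 1.14 between ADREX and SHAM in air, which did not pass over all genes (adjusted p = 0.0788 and 0.0958) and did when adjusted over the list alone. The clock genes Per3 and Npas2 changed in air by 3.10 and −3.27, in a list of 17 in which 4 rose and 2 fell over all genes and 8 rose and 3 fell when adjusted over the list alone. Without SHAM air 4, ADREX air 65, ADREX air 66 or ADREX air 68 these 6 became 2.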
